A study of Homo sapiens with 4 samples.

How the data were processed

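RNA from 4 cultures of passage 3 human preadipocytes was sequenced, 1 library for each combination of transfection (control or PTH2R knockdown) and medium (growth or differentiation), taken after 24 h. Groups were read from the sample titles. Libraries were made with a TruSeq HT kit, per the labels' protocols, and strandedness is not given in the sources used here. The labels disagree on the reagent, with shRNA in the titles and Silencer Select siRNA delivered with Lipofectamine RNAiMAX in the treatment protocol.

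The data were 2 tables of the authors' comparisons, one per medium, each with values for its control and its knockdown library. The submitters' processing notes name the genome build hg19, Bowtie2 2.2.5 and Partek, with no role or order. The annotation and the normalization method are not given in the sources used here. Per the file headers, the authors' value per library is a least squares mean, which with 1 library per group is that library's own value. These deposited values are a scaled signal: in the 1048 genes whose total is whole, every value is a whole multiple of 1 step per library, within 0.05 of a read, and over all genes 54.8% to 64.8% of values are whole, so reads shared between genes were split. The step, the worth of 1 read, was 0.00727 and 0.00854 scaled reads in control and knockdown cells in growth medium and 0.0124 and 0.0115 in differentiation medium. Columns sum to 0.904, 0.871, 1.14 and 1.06 M (1e6). The deposited total reads are estimated counts that need not be whole, and in all 13312 genes they exceed the sum of the 4 libraries. The authors' deposited tables also give a p-value with a step-up FDR, a ratio of knockdown to control, and the signed fold change as a score, minus the inverse of the ratio where it is under 1. The p-value equals a Wald test of a pair of Poisson counts applied to the scaled values, within 9.05e-06. Sex-linked genes that could describe a donor were left out. PTH2R, PTH and PTH2 were not analysed here.

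Of the genes analysed, 12812 carry a symbol, of which 12802 (99.9%) were found in the reference name tables, 480 carry a clone name and 20 a date in place of a symbol. Loci without a symbol were counted and not named. The files use hg19 and the reference is GRCh38, so no coordinates are given.

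Estimated reads per gene were the scaled value divided by the worth of 1 read, and they sum to 124, 102, 92.3 and 91.9 M per library. Ratios carry an exact (Clopper-Pearson) 95% interval from those reads, for counting error only. Log2 fold changes were taken on the deposited scaled value plus a pseudocount of 1, which understates the change of genes at low levels. For each of 4 comparisons, genes with 5 or more scaled reads in the higher library were counted as at least 2-fold higher or lower, with no p-value, since each group is 1 library. The average effects of knockdown and of medium were tested with limma 3.58.1 (trend, R 4.3.3) on the log2 values, with both as additive terms and 1 residual degree of freedom, for genes with 5 or more scaled reads in at least 2 libraries, and Benjamini-Hochberg adjustment at 0.05. The plan named edgeR for counts or for reads recovered from the values, and limma for values that are only normalized. Since the deposited values are scaled, limma was made the main test, which departs from the plan where reads can be estimated. The edgeR test on estimated reads was run as an alternative. The interaction of knockdown and medium is the residual of the limma fit and was not tested. In data simulated for the knockdown comparison at the dispersion edgeR 4.0.16 estimated from the additive fit (0.0099), limma recovered 67.9% of the genes planted at 1.5-fold and 100% of those at 2-fold, with 4 and 7 false calls. For the medium comparison it recovered 77.2% and 99.5%, with 10 and 8 false calls. The simulation gave every gene the same dispersion and no interaction of knockdown and medium, so these shares can overstate recovery in the real libraries. There, 0 of 11247 genes were called for knockdown, although 4 were at least 2-fold different in the same direction in both media.

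The 25 gene lists, the rule for named genes, the groups, the comparisons, the size rule and the first set of alternatives were fixed before the data were examined. Named genes are DCN first, then those at least 2-fold different in the same direction in both media, the 5 highest and 5 lowest of each knockdown comparison, the 10 highest and 10 lowest of the medium comparison in control cells and the 3 highest and 3 lowest of that in knockdown cells, up to 4 members of each list with the largest change in the comparison described, and the 10 largest changes the test called. Other genes named (PLIN1, PPARG, HSPA5, IL6 and ICAM1 where they fall outside the rule, and those of the closing section) were chosen after their values were seen. A list's percentile is the place of its median among 10000 random lists of the same size drawn in 10 bins of mean expression, and describes these libraries.

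Alternatives were median-ratio scaling, DESeq2-type size factors of the estimated reads computed in Python, pseudocounts 5 times smaller and larger, no floor and a floor 4 times higher, 1.5-fold and 3-fold rules, random lists without matching, limma with robust variance or median-centred values, and, chosen after seeing the data, edgeR's quasi-likelihood test on estimated reads rounded to whole numbers, the authors' test on estimated reads, and counts without genes that carry a 7-base word. For that word, 3′ UTRs and coding sequences came from GENCODE 29. Log2 fold changes were clipped at 1.5 either way and adjusted by regression for 3′ UTR length and GC content. The 16057 words of 7 bases with at least 50 carriers were ranked by z. This compares the mean adjusted value of 3′ UTR carriers with that of the other genes. It used the 8986 genes above the floor in both media with a 3′ UTR of at least 50 bases. Mean log2 fold changes of carriers are printed without this adjustment. On simulated data a planted shift of −0.1 put its word at rank 1 of 16057. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.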

Results

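RNA sequencing was carried out on human preadipocytes, the fat cell precursors of adipose tissue, at passage 3 and from a single source. The cells were transfected with a control RNA or with an RNA directed against PTH2R, the parathyroid hormone 2 receptor, and were then kept in preadipocyte growth medium or in adipocyte differentiation medium. Total RNA was taken after 24 h. The labels name the reagent as an shRNA in the sample titles and as an siRNA in the treatment protocol, and "knockdown" is used here for either. Each of the 4 groups was 1 library, so a difference between any pair of libraries has no replicate check. The control and knockdown libraries in growth medium held 124 and 102 M estimated reads (M, 1e6), and those in differentiation medium held 92.3 and 91.9 M. Levels are the authors' scaled estimated reads, which sum to near 1e6 per library, for 13312 genes. The 10 most abundant genes took 8.79% and 8.05% of the reads in growth medium and 14.6% and 12.8% in differentiation medium, led by MMP3 in growth medium and by SCD in differentiation medium.

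The study asks about PTH2R and decorin expression in wound repair. PTH2R was not analysed here, nor were its ligand PTH2 and the hormone PTH, so the loss of the targeted transcript was not checked and the knockdown libraries are named by their labels alone. Decorin (DCN), a small leucine-rich proteoglycan that binds collagen fibrils, was measured at 696 scaled reads in control and 566 in knockdown cells in growth medium. That is a ratio of 0.813, with a 95% counting interval of 0.805 to 0.821, and a log2 fold change of −0.30. In differentiation medium DCN was 703 in control and 635 in knockdown cells, a ratio of 0.903 (95% counting interval 0.892 to 0.913) and a log2 fold change of −0.15. The medium left DCN close to level in control cells (log2 fold change 0.01), and the value in knockdown cells was 0.17. Averaged over both media in limma, the knockdown effect on DCN was −0.22 ± 0.08 (log2, SE, 4 libraries), with an adjusted p of 0.374 in limma. The authors' deposited table gives DCN an FDR of 0.0632 in growth medium and of 0.920 in differentiation medium. The DCN 3′ UTR carries the 7-base word GTGCAAG but not the 8-base word GTGCAAGA: the 201 genes with the 8-base word had a mean knockdown log2 fold change of −0.16 over both media, and the 476 with GTGCAAG alone one of −0.05. Counting intervals here cover counting error only, since PCR copies are not independent molecules and cultures were not repeated.

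**Figure D1:**
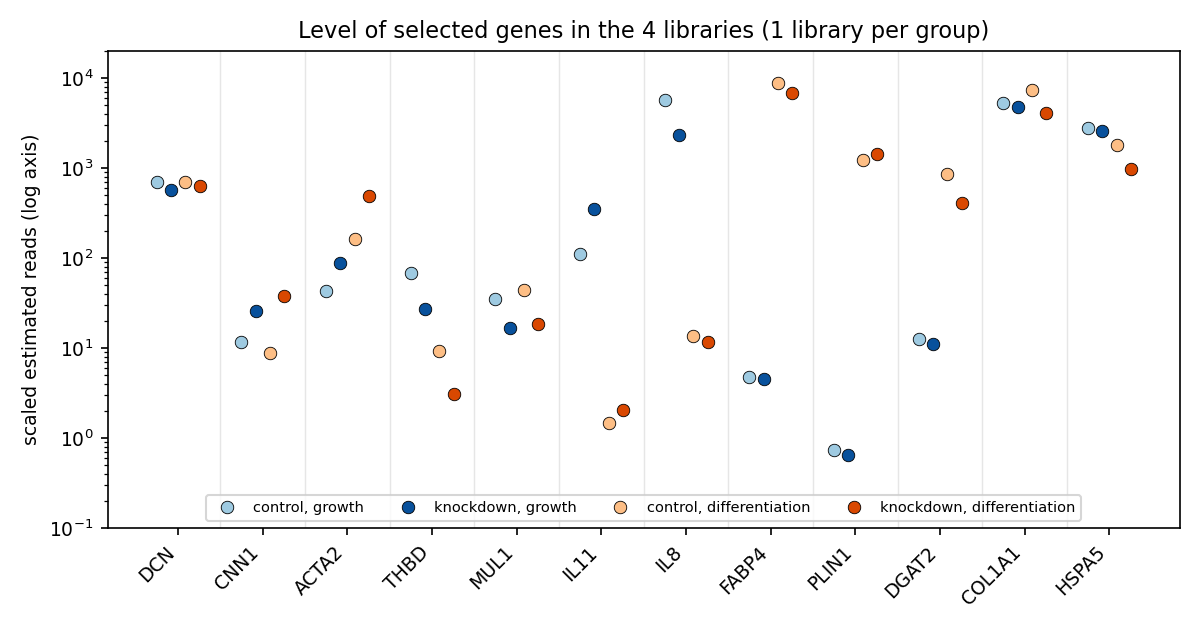
Scaled estimated reads (log axis) of 12 genes, 1 point for each of the 4 libraries. DCN lies between 566 and 703 in every library, CNN1 and ACTA2 are higher in knockdown than in control cells of both media, and FABP4 goes from 4.77 in control cells in growth medium to 8762 in differentiation medium.

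Of the other members of the parathyroid hormone family, PTHLH (parathyroid hormone-like hormone) and its receptor PTH1R were measured. PTH1R rose with differentiation medium by 4.81 ± 0.20 (average log2 change, SE, limma over 4 libraries), from 0.102 to 23.1 scaled reads in control cells. In knockdown cells in differentiation medium it stood at 38.9, a ratio of 1.68 to control (95% counting interval 1.59 to 1.78). PTHLH fell with differentiation medium (−2.13 ± 0.12), and was 5.70 in control and 7.88 in knockdown cells in growth medium. Knockdown called neither gene in limma, over all genes or adjusted over the list alone.

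In growth medium, knockdown cells differed little from control cells. Interleukin 11 (IL11), a cytokine of fibroblasts, was 3.16-fold higher in knockdown cells (95% counting interval 3.10 to 3.22), at 347 against 109.8 scaled reads. The integrin subunit ITGB8 was 2.77-fold higher, the secretory granule protein PTPRN 2.24-fold, the prostaglandin E synthase PTGES 2.21-fold and the smooth muscle calponin CNN1 2.22-fold. Lower in knockdown cells were the neuronal pentraxin NPTX1 by 3.83-fold, the synaptotagmin SYT7 by 2.65-fold, the anticoagulant receptor thrombomodulin (THBD) by 2.46-fold, and the keratin KRT19 by 2.61-fold. The neutrophil chemokine IL8 (CXCL8) was 2336 in knockdown against 5682 in control cells, 2.43-fold lower with a 95% counting interval of 2.42 to 2.44.

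Of 10748 genes with at least 5 scaled reads in the higher library, 10 were at least 2-fold higher and 9 at least 2-fold lower in knockdown cells in growth medium, and 94.4% lay within a ratio of 5 to 4 either way. The count rested on the size chosen: 95 genes passed a 1.5-fold rule and 3 a 3-fold rule, and 7 passed the 2-fold rule when a 5 times larger pseudocount was added to each value.

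The matrix lists moved by small amounts in growth medium. The small leucine-rich proteoglycans had a median log2 fold change of −0.30 over the 3 members measured above the floor, at percentile 0.71 of 10000 random lists of like expression, with lumican (LUM) at −0.40, DCN at −0.30 and biglycan (BGN) at 0.11. Matrix proteases and their inhibitors had a median of −0.12 over 18 genes (percentile 0.44), with the interstitial collagenase MMP1 at −0.52, the urokinase PLAU at −0.40 and ADAMTS1 at −0.38, while ADAMTS2, which trims procollagen, was at 0.42. Collagens and structural matrix genes had a median of 0.00 over 24 genes (percentile 90.4), with COL1A1 at −0.15 and elastin (ELN) at 0.50. Stromal progenitor markers had a median of −0.16 over 9 genes (percentile 0.62), led by the platelet-derived growth factor receptor PDGFRA at −0.71 and by S100A4 at −0.44.

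The insulin and insulin-like growth factor genes stood lower in the knockdown library in growth medium, with a median of −0.27 over 10 genes (percentile 0.00). The binding protein IGFBP3 was at 38.2 against 74.6 scaled reads, and the log2 fold changes of IGFBP5, IGFBP6 and the glucose transporter SLC2A1 were −0.38, −0.31 and −0.40. Genes induced by cyclic AMP, the second messenger of this receptor class, had a median of 0.19 over 8 genes (percentile 99.97), with the kinase SIK1 at 0.47, the phosphodiesterases PDE4D and PDE4B at 0.44 and 0.33, and FOSB at −0.43. A floor 4 times higher left 4 of these genes, with a median of 0.30. The TGF-beta and myofibroblast list had a median of 0.09 over 16 genes (percentile 99.84), with CNN1 and smooth muscle actin (ACTA2) past 2-fold. Inflammatory genes gave a median of −0.04 over 17 genes (percentile 42.7), in which IL8 at −1.28 and the adhesion molecule ICAM1 at −0.61 stood beside IL6 at 0.00. Medians of the wound growth factors (0.04), adipogenic transcription factors (0.06), adipocyte genes (−0.09) and unfolded protein genes (0.03) lay within 0.1 of 0, as did those of the cell cycle (0.02) and interferon response (−0.05).

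In differentiation medium the knockdown library stood further from its control. Genes of the smooth muscle contractile apparatus were among the highest: the myosin heavy chain MYH11 was 18.9 in knockdown against 2.70 scaled reads in control cells (95% counting interval of the ratio 6.07 to 8.10), CNN1 was 4.28-fold higher and the enteric actin ACTG2 4.11-fold. CORIN, the protease that activates natriuretic peptide, was 4.25-fold higher and the synaptotagmin SYT11 3.67-fold. Lower in knockdown cells were the antiviral synthetase OAS1 by 3.11-fold, the protease inhibitor SERPINE2 by 3.12-fold, the peroxisomal thiolase ACAA1 by 2.93-fold, PDZD2 by 2.91-fold and the alkaline phosphatase ALPL by 2.69-fold. The 3′ UTR of ACAA1 carries the word GTGCAAGA.

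Of 10662 genes, 57 were at least 2-fold higher and 44 at least 2-fold lower in knockdown cells in differentiation medium, and 79.9% lay within a ratio of 5 to 4 either way. With a floor 4 times higher the split was 25 higher and 39 lower, and with a 5 times larger pseudocount 49 genes passed.

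Adipocyte lipid and hormone genes stood lower in the differentiated knockdown library, with a median of −0.36 over 22 genes (percentile 0.00), 7 of them at least 1.5-fold lower and 0 at least 1.5-fold higher. The triglyceride synthase DGAT2 was 411 against 852 scaled reads (2.07-fold lower), and the gluconeogenic enzyme PCK1, the lipid droplet protein PLIN4 and the angiopoietin-like ANGPTL4 had log2 fold changes of −0.87, −0.74 and −0.71. Perilipin 1 (PLIN1), which coats the same droplets, was at 0.22. The 13 adipogenic transcription factors had a median of −0.03 (percentile 51.4), with CEBPA at −0.76 and SREBF1 at −0.62 against PPARGC1A at 0.83 and EBF2 at 0.56. PPARG, the master regulator of fat cell formation, was 268 in knockdown and 273 in control cells.

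Genes of the unfolded protein and ATF4 response had the lowest median, among lists with 3 or more genes above the floor, in differentiated knockdown cells, −0.73 over 15 genes (percentile 0.00), with 9 at least 1.5-fold lower. The chaperone cofactor DNAJB9 was at −1.12, the serine synthesis enzyme PSAT1 at −1.03, PHGDH of the same pathway at 64.6 against 131 scaled reads, and the chaperone HSPA5, known as BiP, was 976 against 1780.5 scaled reads (log2 fold change −0.87). In growth medium the list had a percentile of 93.7, and whether the media differed was not tested. Inflammatory genes had a median of −0.53 over 10 genes (percentile 0.00), with TNFAIP6 at −1.29, CXCL1 at −0.95 and the NF-kB inhibitor TNFAIP3 at −0.78, each at 36.5 scaled reads or fewer. Insulin and insulin-like growth factor genes had a median of −0.34 over 13 genes (percentile 0.01), with IGFBP3 at −0.82 and IGF1 at −0.85. The interferon response list had a median of −0.09 over 10 genes (percentile 14.5), although OAS1 stood in it, and the medians of the matrix proteases (0.02), wound growth factors (−0.08), cyclic AMP-induced genes (−0.04), glucocorticoid-induced genes (−0.04) and cell cycle genes (0.12) were small.

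Collagens and structural matrix genes had a median of −0.21 over 25 genes in differentiated knockdown cells (percentile 0.76). COL1A1, the main chain of fibrillar collagen I, was 4090.1 against 7386 scaled reads (log2 fold change −0.85), the crosslinking enzyme LOX was at −0.80 and COL3A1 at −0.64. The small leucine-rich proteoglycans had a median of −0.08 over 6 genes (percentile 28.3), with BGN at −0.38 and PODN at 0.96. Stromal progenitor markers went both ways around a median of −0.05: the growth factor receptor PDGFRB was 581 against 279.8 and NT5E, which encodes CD73, 68.7 against 36.9, whereas endoglin (ENG) was at −0.67. The TGF-beta and myofibroblast list had a median of −0.02 over 15 genes (percentile 61.4), in which ACTA2 was at 1.60 and transgelin (TAGLN) at 0.68, but the TGF-beta target PMEPA1 at −1.12.

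Markers of mural cells were measured, and those of endothelial, leukocyte and epithelial cells were few. The mural cell markers had a median of 0.19 over 6 genes in differentiated knockdown cells (percentile 96.8) and of 0.03 in growth medium, and MYH11, which is also a contractile gene, was the member past 2-fold. With a floor 4 times higher the median in differentiated knockdown cells was 0.01 over 4 genes (percentile 66.3), and 0 passed 2-fold. The leukocyte list had 1 member above the floor, CD68, at −0.20 in growth and −0.14 in differentiation medium. The endothelial list was represented by TEK in growth medium (−0.20) and by EGFL7 in differentiation medium (−0.98). Of the epithelial and mesothelial list, KRT19 and KRT18 were at −1.06 and −0.26 in growth medium, and no member passed the floor in differentiation medium.

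Across both media, 4 genes were at least 2-fold different in the same direction, where 0.015 higher and 0.014 lower would be shared by independent lists of the same sizes. CNN1 and ACTA2 were higher, with ACTA2 at 88.0 against 42.8 scaled reads in growth medium and 492 against 162 in differentiation medium. THBD and the mitochondrial ubiquitin ligase MUL1 were lower, with MUL1 at 16.8 against 34.9 and 18.5 against 44.2. The 3′ UTR of MUL1 carries the word GTGCAAGA, and that of THBD does not carry GTGCAAG. At 1.5-fold, 17 genes were higher and 21 lower in both media, where independent lists would share 0.73 and 0.83. The 4 genes at 2-fold became 3 with median-ratio scaling, size factors or a floor 4 times higher and 0 with a 5 times larger pseudocount, the 38 at 1.5-fold became 18 with that floor and 22 with that pseudocount, and 0 passed a 3-fold rule. Across 9872 genes the log2 fold changes of the media correlated at a Pearson r of 0.47 and a Spearman rho of 0.46, with genes that are not independent replicates. The pair of comparisons shared no library.

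**Figure D2:**
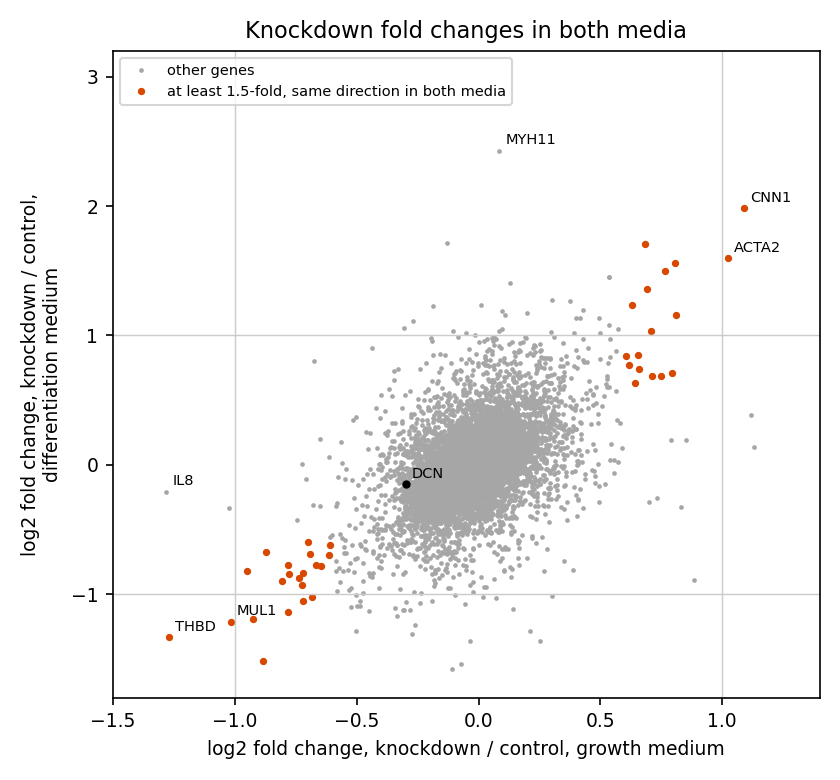
Log2 fold change of knockdown over control in growth medium (x axis) against differentiation medium (y axis) for the 9872 genes above the floor in both, 1 point per gene. The 38 genes at least 1.5-fold different in the same direction are coloured, with CNN1, ACTA2, THBD and MUL1 at the 2-fold lines (grey) or beyond them on both axes, and DCN (black) at −0.30 and −0.15.

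The average knockdown effect was tested in limma with medium and knockdown as additive terms, which leaves 1 residual degree of freedom. Of 11247 genes, 0 passed an adjusted p of 0.05 in limma and the smallest adjusted p was 0.318. At an unadjusted p under 0.05 limma gave 1488 genes, where chance gives 562, and edgeR on estimated reads called 0 of 13312 genes with 1576 at an unadjusted p under 0.05. Adjusted over the list alone, limma called 5 members of the TGF-beta and myofibroblast list, which all rose: CNN1 (1.54 ± 0.23), ACTA2 (1.31 ± 0.15), TAGLN (0.61 ± 0.08), TPM1 (0.45 ± 0.11) and TGFB2 (0.42 ± 0.10). Of these, 4 encode contractile or actin-binding proteins. Adjusted over the list alone, 4 genes of the insulin list fell, among them IGFBP3 (−0.89 ± 0.08), SLC2A1 (−0.51 ± 0.09) and IGFBP4 (−0.45 ± 0.10). So did 3 inflammatory genes, ICAM1 (−0.61 ± 0.07), CXCL5 (−0.56 ± 0.07) and CXCL3 (−0.63 ± 0.13), and the adipocyte fatty acid transporter CD36 (−0.65 ± 0.07). The other 21 lists had 0 calls for knockdown adjusted over the list alone. The authors' deposited table holds 50 genes under an FDR of 0.05 in growth medium and 308 in differentiation medium, from a test of each pair of libraries that took the scaled values as counts; the same test on estimated reads gave 7129 and 8361 genes, and it compares those libraries, not the conditions.

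Differentiation medium changed most of the transcriptome. The genes of the mature fat cell went from near absence to high levels: the fatty acid binding protein FABP4 from 4.77 to 8762 scaled reads in control cells, the hormone adiponectin (ADIPOQ) from 4.32 to 7179, lipoprotein lipase (LPL) from 2.65 to 4563 and PLIN4 from 3.05 to 4846. GPD1, PLIN1, AOC3, THRSP, CIDEC and PCK1 completed the 10 named genes with the largest increase, at log2 fold changes of 9.87 to 8.78. The largest decreases were in secreted and inflammatory genes: MMP1 was 11442 in growth and 24.7 in differentiation medium, the cytokine IL6 1509.9 and 2.79, IL8 5682 and 13.7, and the granulocyte factor CSF3 842 and 0.917, and the log2 fold changes of SERPINB2, PLAU, IL1B, LIF, CXCL5 and PTGS2 ran from −8.69 to −7.59.

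In control cells 1616 of 11356 genes were at least 2-fold higher and 1742 at least 2-fold lower in differentiation medium, and 31.6% lay within a ratio of 5 to 4 either way. Knockdown cells gave like counts, 1644 higher and 1636 lower of 11411, with FABP4 (10.26), ADIPOQ (10.22) and LPL (9.82) at the top and IL6 (−8.72), CSF3 (−8.47) and IL1B (−8.09) at the bottom. In limma, with the knockdown term in the model, 8182 of 11247 genes changed with the medium, 3971 upward and 4211 downward. FABP4 rose by 10.42 ± 0.10, ADIPOQ by 10.31 ± 0.08, LPL by 10.06 ± 0.13, PLIN4 by 9.90 ± 0.17, PLIN1 by 9.59 ± 0.10, GPD1 by 9.58 ± 0.15, AOC3 by 9.24 ± 0.11 and CIDEC by 8.71 ± 0.09 (log2, SE), while IL6 fell (−8.68 ± 0.07) and CSF3 (−8.62 ± 0.10), with limma adjusted p values between 1.16e-05 and 1.59e-05. These p values measure the spread that the additive model left among 4 single libraries. The counts for each list were the same over all genes and adjusted over the list alone.

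All 22 adipocyte lipid and hormone genes rose with differentiation medium, with a median log2 fold change of 6.72 in control and 6.30 in knockdown cells. Of 13 adipogenic transcription factors 9 rose and 3 fell: CEBPA rose by 5.02 ± 0.24, STAT5A by 4.54 ± 0.07, PPARG by 4.23 ± 0.08 and KLF15 by 3.81 ± 0.11, whereas the early factors CEBPB and CEBPD fell (−0.35 ± 0.07 and −0.63 ± 0.09). All 16 sterol synthesis genes rose, among them MVD by 4.57 ± 0.12 and HMGCS1 by 3.69 ± 0.07. Of 16 genes induced by glucocorticoids, a usual component of such media, 10 rose and 5 fell, with FKBP5 up by 5.32 ± 0.08, TSC22D3 by 4.51 ± 0.08 and PDK4 by 7.45 ± 0.10, and the metallothionein MT2A down (−3.82 ± 0.15). In the insulin and insulin-like growth factor list 8 of 13 genes rose, including the insulin-regulated glucose transporter SLC2A4 by 4.74 ± 0.12 and IGF1 by 2.72 ± 0.21, and 4 fell. Of 9 cyclic AMP-induced genes 4 rose and 5 fell, with PDE3A at 2.97 ± 0.17 and PDE4B at −2.87 ± 0.13.

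Proliferation and immune genes fell. All 22 cell cycle genes fell, the ribonucleotide reductase subunit RRM2 (−5.81 ± 0.08), the proliferation marker MKI67 (−5.38 ± 0.13) and PCNA (−0.70 ± 0.10). All 20 interferon response genes fell, including MX1 (−6.57 ± 0.18), IFI27 (−6.53 ± 0.14) and OAS3 (−5.58 ± 0.08), and all 17 inflammatory genes fell, including IL1B (−8.14 ± 0.07) and CXCL1 (−7.58 ± 0.24). Of 14 wound growth factors 11 fell and 2 rose, with the epidermal growth factor receptor ligand EREG down (−6.42 ± 0.21), FGF2 (−4.24 ± 0.08) and ANGPT1 up by 2.73 ± 0.10.

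Matrix genes changed in both directions. Of 24 collagens and structural matrix genes 14 rose and 5 fell: the basement membrane chains COL4A1 and COL4A2 rose by 4.40 ± 0.15 and 3.67 ± 0.09, COL15A1 by 3.65 ± 0.10 and ELN by 3.60 ± 0.20, whereas the matricellular gene TNC fell (log2 fold change −3.37 in knockdown cells). Of 19 matrix proteases and inhibitors 15 fell and 3 rose, with the stromelysin MMP3 down (−6.25 ± 0.12) and MMP10 (−5.81 ± 0.10), and ADAMTS2 up by 1.85 ± 0.07. Of 16 TGF-beta and myofibroblast genes 11 fell and 2 rose: INHBA, a subunit of activin A, fell (−6.09 ± 0.12), and ACTA2 and TAGLN rose by 2.18 ± 0.15 and 0.79 ± 0.08. Of 5 small leucine-rich proteoglycans tested, ECM2 and FMOD rose by 3.90 ± 0.18 and 2.74 ± 0.10, LUM and BGN fell (−0.59 ± 0.11 and −0.92 ± 0.14), and DCN did not pass (adjusted p = 0.367 in limma). The median of this list in knockdown cells was 1.45 over 6 genes and −0.12 with a floor 4 times higher, which left 4. Of 9 stromal progenitor markers 5 fell and 2 rose, with NT5E down (−4.20 ± 0.21) and DPP4 (−3.62 ± 0.08). Of 6 mural cell markers 5 rose, with MCAM at 2.65 ± 0.08.

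Stress and quality lists held genes that moved in either direction with the medium. Of 15 unfolded protein and ATF4 response genes 6 fell and 3 rose, with ATF3 down (−3.28 ± 0.24) and PSAT1 up by 2.35 ± 0.27. Of 12 p53 targets 5 rose and 4 fell, with ZMAT3 at 1.82 ± 0.09 and the stress cytokine GDF15 at −4.28 ± 0.09. Of 10 heat shock genes 4 rose and 2 fell, HSPA1B rising by 0.84 ± 0.09 and HSPH1 falling (−1.26 ± 0.07). Of 6 replication-dependent histone genes HIST2H2BE rose, by 1.31 ± 0.07, and 5 did not pass; the near-identical members of this family, like HSPA1A and HSPA1B, can share reads. The nuclear RNAs MALAT1 and NEAT1, the measured members of the RNA quality list, rose by 1.69 ± 0.08 and 1.62 ± 0.14, and their knockdown log2 fold changes were 0.28 and 0.08 in growth medium and 0.15 and −0.43 in differentiation medium. TEK and KRT18, the members tested of the endothelial and the epithelial lists, fell (−3.10 ± 0.13 and −2.75 ± 0.10), and CD68 of the leukocyte list did not pass. For knockdown, the p53, sterol and heat shock lists had medians of −0.03, −0.02 and −0.08 in growth medium and of 0.07, 0.02 and −0.17 in differentiation medium, and the histones had −0.05 and −0.10.

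**Figure D3:**
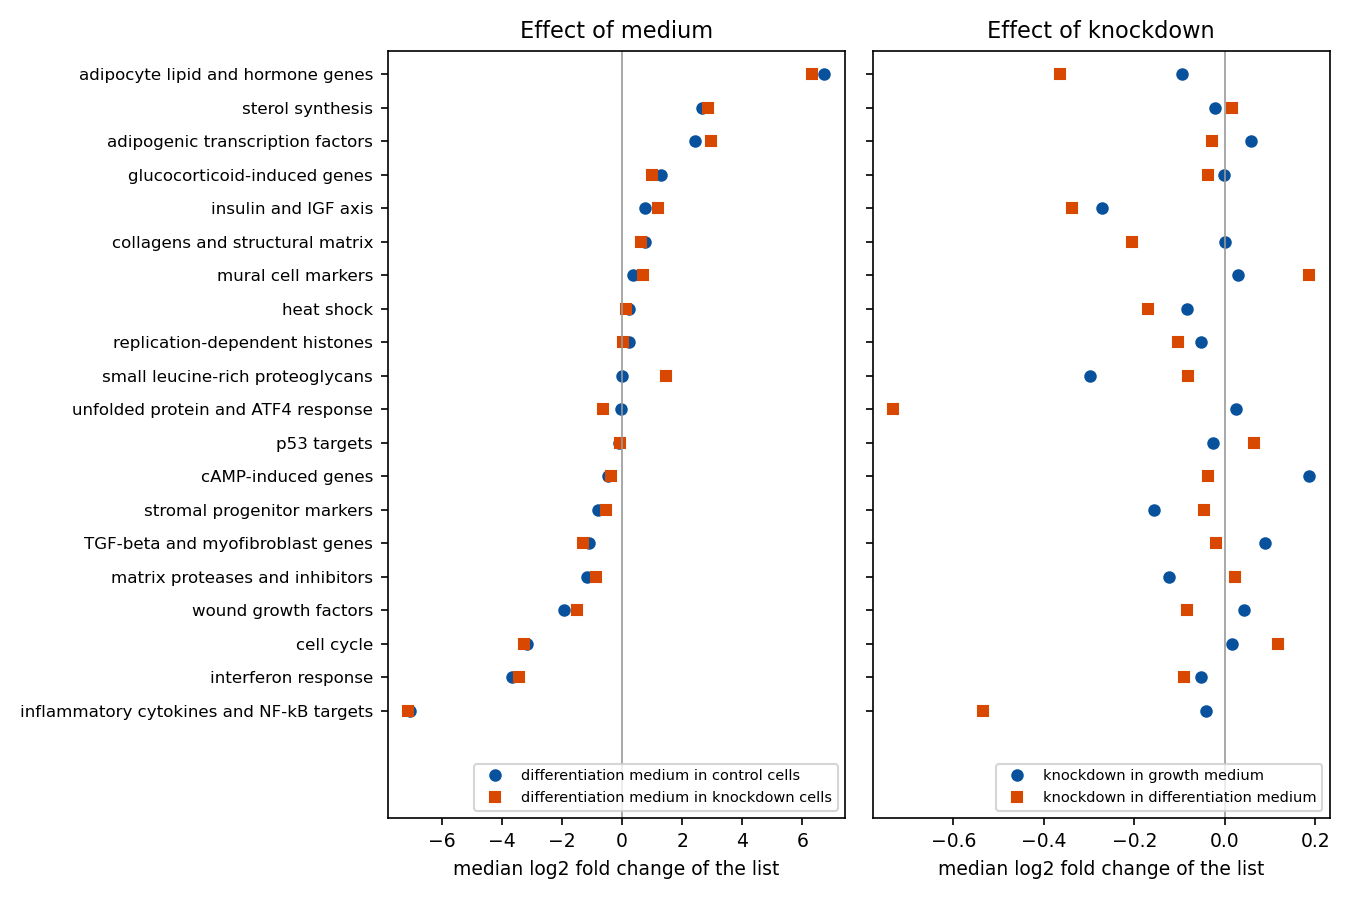
Median log2 fold change of each gene list with a percentile, for differentiation over growth medium (left) and for knockdown over control (right, on a narrower axis), 1 point per list and comparison. The medium moved the inflammatory list to −7.04 and the adipocyte list to 6.72 in control cells, and the lowest knockdown median was −0.73 for the unfolded protein list in differentiation medium.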

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

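The total reads that the authors' deposited tables give for each gene exceed the reads of the 4 libraries in all 13312 genes. Of 609 M (1e6) total reads, the 4 libraries account for 411 M, and 198 M, or 32.6%, lie outside them and are not used here. This was picked out because it is a signal in a column that the comparisons do not use. Across genes, which are not independent replicates, the log2 of this remainder correlated with the 4 libraries at a Pearson r of 0.93 and 0.93 in growth medium and 0.92 and 0.92 in differentiation medium. No explanation was tested.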

How the results depend on the processing

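The alternatives chosen after the results were seen were edgeR on estimated reads, the authors' test on estimated reads and the counts without genes carrying the word GTGCAAG. The plan had named edgeR as the main test for recovered reads. With the 2-fold rule, knockdown counts were 7 in growth and 49 in differentiation medium with a 5 times larger pseudocount, and 64 in differentiation medium (25 higher, 39 lower) with a floor 4 times higher. At 1.5-fold and 3-fold the counts were 95 and 3 for knockdown in growth medium, 651 and 7 in differentiation medium, 5536 and 1968 for medium in control cells and 5442 and 1897 in knockdown cells, and 38 and 0 genes had the same direction in both media, since the rule itself moved. DCN kept its direction: −0.27 and −0.28 for knockdown in growth medium with median-ratio scaling and with size factors, −0.13 in differentiation medium with median-ratio scaling, and 0.0319 for medium in control cells with size factors. The correlation of the knockdown fold changes was 0.52 with a floor 4 times higher and 0.45 without genes carrying the word. Of the list medians outside the central 95% of random lists, 1 changed sign, the small leucine-rich proteoglycans for medium in knockdown cells, −0.12 with a floor 4 times higher, which left fewer genes. Medians nearer 0 also changed sign: the same list in control cells (−0.33), collagens (−0.04) and mural markers (−0.03) for knockdown in growth medium, p53 targets (0.00) and histones (−0.05) for medium in knockdown cells, and, with median-ratio scaling, the sterol (0.01), p53 (0.00) and glucocorticoid (0.03) lists for knockdown in growth medium. For the others the cause was not tested. With that floor 62 of 80 list medians stayed within 0.1. Against unmatched lists no percentile crossed the bounds of the central 95%, though that of the sterol list for knockdown in differentiation medium went from 91.5 to 69.2. No named gene past 2-fold changed sign under scaling or pseudocount. The calls for knockdown stayed at 0 in limma without a floor, with median centring, robust variance or either pseudocount, and in edgeR, and those for medium lay between 8136 and 9322. Libraries of a medium were matched by the medium term of the additive fit, and there were no replicate pairs. Leaving a library out would leave no residual degree of freedom. Not run: limma with the higher floor or with size factors, another unit, summing of repeated symbols, PTH2R, and the likelihood ratio and DESeq2 tests meant for raw counts.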

Other observations

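Of the 62 genes that differentiation medium raised at least 64-fold in control cells, many lie outside the adipocyte list. The protease inhibitor A2M went from 0.330 to 399 scaled reads, the alcohol dehydrogenase ADH1B from 0.284 to 450.3, the lipoprotein APOE from 3.53 to 1848, the retinol carrier RBP4 from 1.21 to 509, and KLB, the coreceptor of FGF21, from 1.91 to 238. The matrix protein DPT went from 0.916 to 123. In knockdown cells the BMP antagonist CHRDL1 was 556 against 355 in control cells, and ITIH5 121 against 309. Further genes at least 1.5-fold higher in knockdown cells of both media were the receptor tyrosine kinase MET (64.8 against 37.8 scaled reads in growth and 17.9 against 5.69 in differentiation medium), the activin receptor ACVR2B (log2 fold changes 0.79 and 0.71), the neurofilament NEFL (0.64 and 0.63) and the atrophy-related ubiquitin ligase FBXO32 (0.71 and 1.04). MYOCD, the coactivator of smooth muscle genes, was 21.7 against 10.3 in growth medium and lay below the floor in differentiation medium. These genes were chosen after their values were seen.

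In the hypotheses that follow, the tests chosen after the result was seen were the rank of the word in the other medium, the share of strongly raised genes, and the counts without genes carrying the word; the seed shares of contractile and adipocyte genes were recomputed over genes above the floor in differentiation medium, as first written, after values over genes above the floor in both media were seen (2 of 11 and 0 of 3).

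Genes lower in knockdown cells of both media shared a 3′ UTR word. Of the 21 genes at least 1.5-fold lower in both, 19 had a 3′ UTR to search, and 13 (68.4%), among them MUL1, ACAA1, ARNT, PRKAR1A and SGK3, carry the 8-base word GTGCAAGA, against 2.24% of 8986 genes, while THBD, IGFBP3, CD36, ICAM1, CYGB and NKD2 do not; after library scaling by median ratios 19 genes were lower in both, a count that factors so near 1 (0.991 to 1.01) could hardly change, so it is no test of scaling. A candidate explanation is silencing through seed matches of the transfected siRNA, whose sequence was not used here: of 16057 words of 7 bases, GTGCAAG had the lowest carriers in growth medium (z −11.4), and in the test named seed matches of the transfected siRNA, other medium, it took rank 1 in differentiation medium (z −12.2), whose libraries are separate. Genes with the word in the 3′ UTR alone were lower than those with it in the coding sequence alone by a log2 difference of −0.0648 (SE 0.0129), and carriers of the 8-base word lower than those of only a 7-base word, GTGCAAG or TGCAAGA, by −0.124 (SE 0.0227), with SEs across genes and means that include the medium in which the word was chosen; in differentiation medium alone the means were −0.11 against −0.02 and −0.19 against −0.04. The word and the 21 genes were both picked in part on growth medium values, which favours the 68.4% share and a drop in count without carriers. Without the carriers of GTGCAAG, 8 genes remained lower in both media, including those with no 3′ UTR to search. At 2-fold, 16 genes then passed in growth and 82 in differentiation medium, or 15 and 69 without carriers of either 7-base word. A loss of PTH2R and other effects stay open for the genes that remained. They stay open for the carriers as well, since carrying the word does not settle the cause for a single gene. At the other end, GACGTAA (z 6.39 in growth and 6.86 in differentiation medium), TGACGTA (6.06 and 6.92) and GACAGTA (5.63 and 8.06) had the highest carriers in both media. The highest z in shuffled data with no planted word was 3.82. Carriers among the genes 1.5-fold higher in both media were not counted. DCN carries GTGCAAG alone, and the 476 such genes had a mean of −0.05 with 0 of them 1.5-fold lower in both media, but a part of the word in the −0.30 and −0.15 of DCN was not tested, as a group mean does not settle a single gene.

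Contractile smooth muscle genes were higher in differentiated knockdown cells, with a median log2 fold change of 0.87 over 13 genes, against 0.23 with 3 of them lower in growth medium, in a list written after the values were seen and before its test, including LMOD1 at 1.54, MYLK at 0.87 and SMTN at 0.20. A larger share of mural cells would lift the mural markers that encode no contractile protein, but their median over 5 genes was 0.0794 (interquartile range 0.36), below 0.5 of the contractile median by a margin just over that range, with a bar set by genes picked for being higher, so a larger share stays open; the markers were ABCC9 at 0.47, KCNJ8 at 0.29, NOTCH3 at 0.08, MCAM at −0.06 and CSPG4 at −0.32. Release from seed matches of the control siRNA was examined by words that mark higher genes, GACGTAA, TGACGTA and GACAGTA, picked from these fold changes. Of 12 contractile genes 2 (16.7%, CALD1 and SYNPO2) carry such a word, against 10.5% of all genes. This share is under the bound set against the explanation, and the 10 without such a word kept a median of 0.78. Direct matches of these words can therefore account for few of these genes. Other words with high carriers in both media, such as AGACGTA (z 5.47 and 5.74), were not searched in them. The control sequence was not used here, so direct matches of other words stay open. Release of a gene that acts on the contractile genes would need no word in them, so it stays open. A response to loss of PTH2R may account for the pattern, as may a difference between single cultures, and neither was tested.

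Adipocyte genes were lower in differentiated knockdown cells. Direct seed matches of the transfected siRNA in adipocyte genes, as marked by the word GTGCAAG, can account for few of those lower by 1.5-fold. Of these 7 genes, 1 (14.3%, PCK1) carries the word GTGCAAG, against 7.44% of all genes, and 6 do not. That share lay just under the bound set against the explanation and rests on 1 gene. This test sees only words in the adipocyte genes themselves, so silencing of a gene that acts on them stays open. A smaller share of differentiated cells could lower them together: of the 62 genes raised at least 64-fold by the medium, 28 were lower and 6 (9.68%, 95% binomial interval 3.63% to 19.9%, Clopper-Pearson) higher by 0.25 log2 or more in knockdown cells, with a median of −0.23. That interval takes genes as independent trials, which genes of the same libraries are not. The genes were also picked on the differentiated control library, the reference of this comparison, which favours lower values in knockdown cells. The bound set for a smaller share was 10%, which lies inside the interval. A smaller share and a change within cells therefore cannot be told apart with these few genes. PLIN1, A2M and CHRDL1 stood higher in the same library, and a loss of PTH2R stays open as untested.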
